A study of Mus musculus with 4 samples.

How the data were processed

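The deposited files hold, per library, raw UMI counts of 32285 mouse genes and 7 added sequences in the barcodes that the authors kept, made per the labels with Cell Ranger 5.0.1 on the mm10 genome from 10x Genomics droplet libraries of nuclei from fresh-frozen liver, with formaldehyde added to the homogenate. The deposited counts are not normalised. Of the genes, 32158 were found by identifier in the reference annotation, which gave coordinates. Groups and replicate numbers are those of the labels, with 2 libraries per genotype. Replicate numbers do not pair the libraries by any label, so the tests compare genotypes only.

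Barcodes with at least 500 detected genes were used, which removed none of the 43664, and the highest Scrublet doublet scores were removed per library (0.8% per 1000 barcodes), leaving 39017. Counts were scaled to 10000 per barcode and log-transformed, 2000 variable genes were scaled and clipped at 10, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 26 clusters (Python 3.11.15, scanpy 1.11.5, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). A cluster took a class name when at least 3 marker genes of the class lay 1.5 times or more above the level that free RNA would give, estimated from the 10% of barcodes with the fewest UMIs. 18063 barcodes were named and 20954, whose counts resembled free RNA or mixed classes, were not. Class names mean resemblance to markers. 5 classes had at least 20 nuclei in each library. Endothelial- and mesenchymal-like nuclei were clustered again with 15 principal components on values centred per library, for genes found in at least 10 nuclei, and sub-clusters were named by subtype markers in the same way, with at least 5 UMIs per marker. All mesenchymal sub-clusters took the stellate name by markers raised over free RNA, although 3 of the 8 had portal fibroblast and no stellate markers raised over the other sub-clusters, and a pair were led by endothelial or macrophage genes. The class is therefore not stellate throughout.

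Counts were summed per class and library and fitted with edgeR 4.0.16 (R 4.3.3, filterByExpr, TMM, quasi-likelihood test), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. All tests are two-sided. Shares of nuclei were tested with edgeR on nuclei counts and adjusted over classes or sub-clusters. 32 gene lists made 68 list tests by class with camera (limma 3.58.1, preset correlation 0.01), adjusted over all 68, for lists with at least 5 measured genes. With that preset correlation 27 passed, 17 higher and 10 lower in CKO. None passed with an estimated correlation (smallest adjusted p 0.603) or with fry (0.336), and 5 of the 27 stayed past the threshold with each library left out in turn. Named genes are the targeted gene, the 6 annotated genes with the smallest p per class and the members with the smallest p of each list, of which the text gives a part. Results on a pair of genes are not reported here. Gene lists, tests, filters and the rule for named genes were fixed before the data were examined. Leaving out genes of which free RNA accounts for 0.5 or more was planned. The subtraction of free RNA, the level of 20% for genes of a class's own RNA, the naming rule for clusters and the tests on sub-clusters were chosen after. A test of free RNA on genes picked for being higher in several classes was dropped, because that choice largely fixes its outcome, and replaced by genes of the planned hepatocyte lists. The estimate scales the profile of unnamed barcodes to the secreted hepatocyte transcripts of each class, or to mitochondrial transcripts in hepatocyte-like nuclei. It cannot tell free RNA from RNA held in attached debris. Since unnamed barcodes include some that resemble mixed classes, RNA from nuclei of a class itself can count as free. Unnamed barcodes were 39.3% and 62.7% of kept barcodes in WT replicates 1 and 2, and 62.9% and 57.2% in CKO replicates 1 and 2. All free RNA shares, percents of counts and subtractions rest on this profile. Log2 values within a replicate number use a prior count of 2.

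The fits were tested on simulated data with 200 changed genes per class. At a 4-fold change edgeR recovered 46% (hepatocyte-like) to 84% (cholangiocyte-like) of the genes, at a 2-fold change 6% to 24%, and 10.3% to 12.8% of all calls were false, above the nominal level. The simulated genes vary independently, without differences between libraries shared by many genes, so these rates do not give the power of the real tests. In hepatocyte-like nuclei 80% of simulated 8-fold changes were recovered, while Cyp4a10, with a measured log2 change of 3.14, did not pass over all genes. Alternatives were DESeq2 1.42.0, RLE scaling, no count filter, summed counts of a class thinned to the same total in each library, limits of 300 or 1000 genes and of 1000 UMIs per barcode, no doublet removal, Leiden resolution 2, principal components on values centred per library, genes with mostly free RNA left out, free RNA subtracted, the replicate number as a block, and each library left out. Dendritic, T/NK-, B- and mesothelial-like nuclei were too few in some libraries and were not tested for genes. Intervals for shares are exact 95% Clopper-Pearson intervals.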

Results

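Single-nucleus RNA sequencing was done on livers of male mice fed DDC, a diet that injures bile ducts and brings on a ductular reaction, for 4 weeks from an age of 10 to 11 weeks. 2 libraries came from mice lacking Rbpj, the DNA-binding partner of Notch, in hepatic progenitor cells (CKO) and 2 from wild-type mice (WT). The libraries held 45620141 UMIs in 16000 barcodes (WT replicate 1), 13914845 in 6480 (WT replicate 2), 38003108 in 16000 (CKO replicate 1) and 12261329 in 5184 (CKO replicate 2). Median depth per barcode was 2267, 1722, 2042 and 1896 UMIs in that order. Both first replicates hold exactly 16000 barcodes and more UMIs than both second replicates. Log2 values within each replicate number are therefore given beside pooled ones for the genes and groups that matter most. The labels do not say whether the replicates are separate animals. The p of an edgeR test measures the spread between libraries. The camera p with the preset correlation sets the genes of a list against the other genes of the class, so small values do not measure that spread. A binomial probability covers counting error only.

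The question of the first comparison was whether the cell composition of the injured liver differed between the genotypes. Cholangiocyte-like nuclei made up 23.9% ± 3.29 (SD, n = 2) of the named nuclei other than hepatocyte-like in WT and 10.2% ± 2.14 (SD, n = 2) in CKO livers. The share was 21.6% (95% Clopper-Pearson interval 20.6 to 22.6%) and 26.3% (23.8 to 28.8%) in the WT libraries, and 11.7% (10.7 to 12.7%) and 8.64% (6.35 to 11.4%) in the CKO libraries. Endothelial-like nuclei made up 18.9% ± 0.509 in WT and 24.3% ± 6.50 in CKO livers, macrophage-like nuclei 37.3% ± 4.44 and 43.0% ± 13.3, and mesenchymal-like nuclei 13.4% ± 4.52 and 13.5% ± 5.64 (SD, n = 2 each). These shares are of 6721 and 1214 nuclei in WT and 4251 and 509 in CKO replicates 1 and 2. Hepatocyte-like nuclei made up 12.5% and 17.5% of kept barcodes in the WT and 6.67% and 32.5% in the CKO libraries, so the CKO libraries were unlike each other. No class passed the edgeR test on nuclei counts. The cholangiocyte-like log2 change was -1.23 (SE 0.62, adjusted p = 0.642) among the other non-hepatocyte nuclei and -1.81 (SE 1.28, adjusted p = 0.905) among all kept barcodes. With a library left out the latter ranged from -3.14 (without CKO replicate 1) to -1.13 (without CKO replicate 2). Intervals cover counting error only, and an exact permutation test of 2 libraries against 2 cannot give a p below 0.333.

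**Figure D1:**
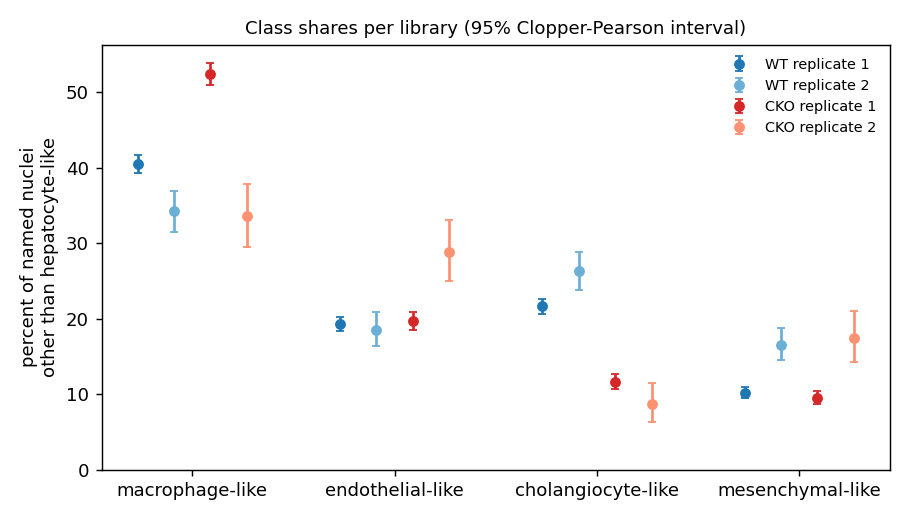
Share of each class among named nuclei other than hepatocyte-like, in percent, with 1 point per library and its 95% Clopper-Pearson interval. Both CKO libraries hold a smaller cholangiocyte-like share (11.7% and 8.64%) than both WT libraries (21.6% and 26.3%), while the other classes overlap or vary within a genotype.

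Rbpj transcripts were compared in each class to see whether the deletion shows in the counts. Rbpj (ENSMUSG00000039191, chromosome 5, 53466152 to 53657362 of GRCm38) stood at 72.5 ± 3.34 CPM in WT and 59.6 ± 21.3 CPM in CKO cholangiocyte-like nuclei (SD, n = 2 each), a log2 change of -0.06 (SE 0.27) on 378, 45, 107 and 4 UMIs in WT replicates 1 and 2 and CKO replicates 1 and 2. The log2 change was -0.61 (SE 0.30) in macrophage-like, -0.30 in mesenchymal-like, 0.08 in endothelial-like and 0.06 in hepatocyte-like nuclei. None passed the test, the smallest p adjusted over the classes alone being 0.357. The labels do not give the deleted exons, and 3' tags from a deleted allele may still be counted, so these values do not test the deletion. Notch targets did not pass the list test in any class. Their median log2 change was 0.17 in cholangiocyte-like nuclei (6 of 16 listed genes measured, adjusted p = 0.0884, Cdkn1a alone passing over the list alone at 0.0462) and 0.11 in endothelial-like nuclei (adjusted p = 0.411). Notch receptors, ligands and cofactors did not pass in any class either, with adjusted p from 0.411 to 0.769.

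In endothelial-like nuclei the comparison asked how the vessel lining differed when Rbpj was missing from progenitor cells. Genes of continuous and large vessels were lower as a group in CKO libraries (10 of 13 measured members negative, median log2 change -0.60, -0.29 and -1.21 within the replicate numbers, camera adjusted p = 5.3e-06, 0.603 with an estimated correlation). Emcn, an endothelial sialomucin among them, had a log2 change of -0.97 (SE 0.26), from 121 ± 6.47 to 60.4 ± 4.02 CPM. Efnb2, an arterial ephrin ligand, had -0.94 (SE 0.27), from 104 ± 0.179 to 51.6 ± 10.3 CPM (SD, n = 2 each). None of these members passed when adjusted over the list alone (smallest 0.0504). Among single genes, Col8a1 (ENSMUSG00000068196), a short-chain collagen, had a log2 change of -3.55 (SE 0.56) on 211, 13, 9 and 0 UMIs in WT replicates 1 and 2 and CKO replicates 1 and 2. Slit3 (ENSMUSG00000056427), a guidance ligand, had -3.33 (SE 0.56) on 116, 14, 7 and 0 UMIs in the same order. Col8a1 and Slit3 also lead a sub-cluster that was less frequent in CKO livers, so these genes and the large vessel list do not tell a change within cells from fewer such nuclei. The genes with the smallest p in the other direction were hepatocyte enzymes, Oat (2.71), Cyp4a10 (3.74) and Cyp4a14 (3.66), for which free RNA accounted for 101%, 92.4% and 101% of the counts.

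3 further endothelial lists were called lower with the preset correlation: sinusoidal identity (13 of 14 negative, median -0.28, adjusted p = 0.0193), angiogenic and tip cell genes (10 of 11, -0.25, 0.00952) and angiocrine factors (11 of 13, -0.23, 0.0487). All had an adjusted p of 0.603 with an estimated correlation. Within the replicate numbers the medians were -0.36 and -0.32, -0.43 and -0.24, and 0.04 and -0.80 in that order. The angiocrine median thus lay above 0 within the first replicates. The pooled changes of the 3 lists were no larger than that of endothelial genes with little free RNA. The 586 genes with under 20% of counts from free RNA had a median log2 change of -0.35, against 0.004 for all 9786 tested genes. This percent is of counts summed over libraries, of which WT replicate 1 gave the most. Genes higher there pass the 20% level more easily, which can lower that median. The estimated share of UMIs that is not free RNA changed by -0.61 on the log2 scale. That share is of raw UMIs, while the gene and list values are TMM-scaled, so they are not on the same scale. The sinusoidal call ended without WT replicate 1 (adjusted p = 0.0638), WT replicate 2 (0.0649) or CKO replicate 1 (0.125), and the angiogenic call without WT replicate 1 (0.224) or CKO replicate 1 (0.183). The angiocrine call ended without WT replicate 1 (0.191), WT replicate 2 (0.147) or CKO replicate 2 (0.748). Adhesion and inflammation genes did not pass (adjusted p = 0.748), nor did TGF-beta response genes (0.622), whose median (0.06) and test differed in sign. The large vessel list was still called with each library left out in turn (adjusted p at most 0.0157) and, as planned, with free RNA genes left out (0.0136). With free RNA subtracted it had a median of -0.45 and was no longer called (adjusted p = 0.0944). edgeR called 0 of 9786 genes, with 483 at an unadjusted p under 0.05, and DESeq2 called 1. Without CKO replicate 1 the edgeR count was 184 and without CKO replicate 2 it was 154.

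Endothelial sub-clusters were compared by their share of endothelial-like nuclei. Sinusoid-type nuclei made up 76.4% ± 0.12 in WT and 78.5% ± 5.40 in CKO livers, and vessel-type nuclei 21.6% ± 0.434 and 21.3% ± 5.15 (SD, n = 2 each), with no detectable difference (adjusted p = 0.901 and 0.467, edgeR). These names rest on markers raised over free RNA. Sub-clusters 3, 4 and 8 of the sinusoid type had 0 of 7 sinusoid markers raised over the other sub-clusters, and Oat was among the leading genes of sub-cluster 4. Within the vessel type, a sub-cluster led by Slc45a4, Vegfc and Mecom made up 10.6% ± 1.12 in WT and 15.9% ± 2.32 in CKO livers, a difference whose call ended with single libraries left out. It shares the leading genes Mecom and Adgrg6 with a sub-cluster led by Col8a1, Dkk2, Slit3, Bmx and Vwf. A different division of nuclei between them is therefore not told from fewer nuclei. The sub-cluster led by Col8a1 was less frequent in CKO livers, at 6.69% ± 0.602 in WT and 1.30% ± 0.871 in CKO (SD, n = 2 each). The log2 change was -1.88 (SE 0.36, edgeR adjusted p = 0.000447 over 10 sub-clusters, chosen for testing after the data were seen). The shares were 6.26% (95% Clopper-Pearson interval 5.0 to 7.72%) and 7.11% (4.12 to 11.3%) in the WT libraries and 1.91% (1.10 to 3.09%) and 0.68% (0.0172 to 3.73%) in the CKO libraries. Without CKO replicate 1 the call ended (adjusted p = 0.118), and the last share rests on 1 of 147 nuclei. A sub-cluster led by Csmd1 and Mmrn1 took no subtype name. Of the 3 lymphatic markers in the data, 2 were raised over free RNA and over the other sub-clusters, and a name needed 3. It held 23, 5, 3 and 0 nuclei in WT replicates 1 and 2 and CKO replicates 1 and 2. Its share was 2.0% ± 0.315 in WT and 0.179% ± 0.253 in CKO livers (log2 change -2.52, SE 0.72, edgeR adjusted p = 0.0112). This call ended without WT replicate 1 (0.0687), CKO replicate 1 (0.308) or CKO replicate 2 (0.0706).

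**Figure D2:**
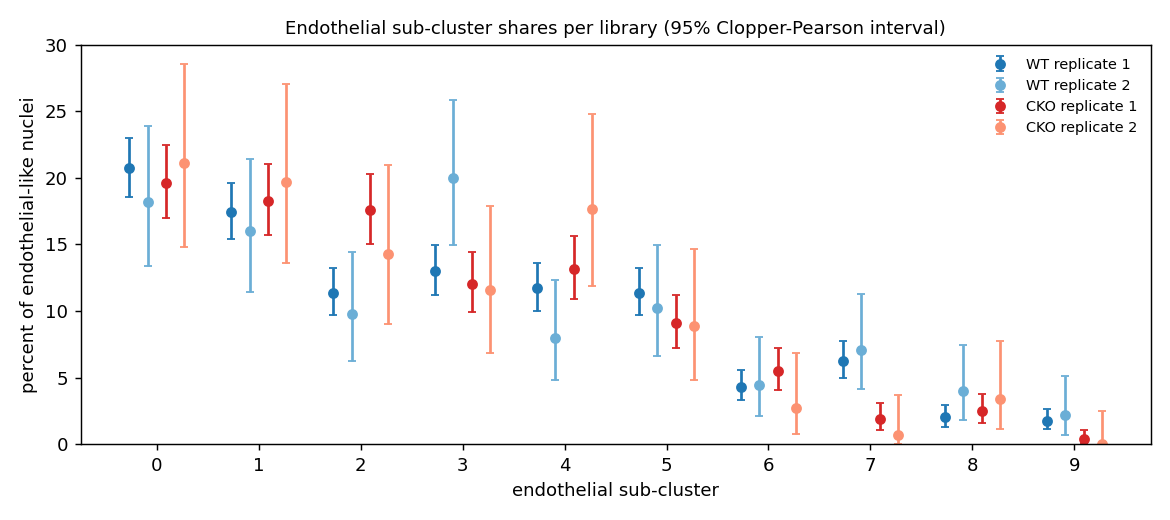
Share of each endothelial sub-cluster among endothelial-like nuclei, in percent, with 1 point per library and its 95% Clopper-Pearson interval. Sub-cluster 7, led by Col8a1, lies at 6.26% and 7.11% in the WT libraries and at 1.91% and 0.68% in the CKO libraries.

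In mesenchymal-like nuclei, which include stellate cells, the comparison asked how the matrix-producing cells differed. Fibrillar collagen and matrix genes were lower as a group in CKO libraries (22 of 25 measured members negative, median log2 change -0.34, -0.32 and -0.44 within the replicate numbers, camera adjusted p = 0.000863, 0.603 with an estimated correlation). Col1a2, a chain of type I collagen, went from 229 ± 21.6 to 122 ± 21.1 CPM (log2 change -0.86, SE 0.27), and Col3a1, the chain of type III collagen, from 524 ± 105 to 287 ± 94.9 CPM (-0.83, SE 0.31; SD, n = 2 each). Neither passed when adjusted over the list alone (smallest 0.176). Mesenchymal genes with little free RNA also had lower values. The 1032 genes with under 20% free RNA had a median log2 change of -0.28, against 0.01 for all 8639 tested genes. The share of raw UMIs that is not free RNA, without TMM scaling, changed by -0.43. The collagen list was still called with each library left out in turn (adjusted p at most 0.0118) and with free RNA genes left out (0.0153). With free RNA subtracted it had a median of -0.27 and was no longer called (adjusted p = 0.15). Contractile and activation genes had 7 of 8 members negative (median -0.30, adjusted p = 0.0375, 0.603 with an estimated correlation), a call that ended without WT replicate 1 (0.0793), CKO replicate 1 (0.0744) or CKO replicate 2 (0.073). With free RNA subtracted this list was not called (0.553) while its median stayed near the same level (-0.28). The mix of sub-clusters in this class differed between libraries, so these values do not tell a change within cells from a change in the mix. A sub-cluster led by Kcnq3, Ltbp2 and Col15a1 made up 23.2% ± 2.37 in WT and 9.98% ± 9.34 in CKO libraries (SD, n = 2 each), which did not pass (edgeR adjusted p = 0.202). Quiescent stellate genes (adjusted p = 0.39) and TGF-beta response genes (0.116) did not pass, and among the latter Ccn2, a matricellular growth factor, had a log2 change of -1.11 (SE 0.38). Genes with the smallest p included Itga8, an integrin of stellate cells (-1.67, SE 0.29, from 245 ± 42.1 to 79.0 ± 10.9 CPM), Pcdh11x, a protocadherin (-1.76, SE 0.32), and Ptprt, a receptor phosphatase (2.22, SE 0.36). Ptprt and Itga8 also mark sub-clusters whose shares were 17.1% and 6.4% in WT and 33.3% and 2.87% in CKO libraries. The smallest p of all belonged to the hepatocyte enzyme Oat (2.40), with 103% of its counts accounted for by free RNA. edgeR called 0 of 8639 genes, with 635 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0823, and DESeq2 called 1. The edgeR count was 231 without CKO replicate 1, 330 without CKO replicate 2, 19 without WT replicate 1 and 11 without WT replicate 2.

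The labels place the deletion in hepatic progenitor cells, whose markers the cholangiocyte-like class shares in part, and the comparison asked how the biliary and progenitor nuclei themselves differed. Biliary and progenitor markers were lower as a group in CKO libraries (16 of 18 measured members negative, median log2 change -0.25, -0.12 and -0.97 within the replicate numbers, camera adjusted p = 0.00179, 0.603 with an estimated correlation). Prom1 (ENSMUSG00000029086), a surface marker of liver progenitors, fell when adjusted over the list alone (adjusted p = 0.00753, log2 change -1.68, SE 0.32, from 129 ± 35.6 to 36.6 ± 4.51 CPM) but did not pass over all genes (0.436). Without CKO replicate 2, which holds 44 of these nuclei, the list was no longer called (adjusted p = 0.115), nor was it with free RNA subtracted (median -0.17, 0.443), while it was with free RNA genes left out (0.0402). The 1611 cholangiocyte genes with under 20% free RNA had a median of -0.23. Cell cycle genes were also lower as a group (10 of 14 negative, median -0.49, -0.30 and -3.54 within the replicate numbers, adjusted p = 0.00396, 0.603 with an estimated correlation), which rested on CKO replicate 2 (0.748 without it). Fstl4 (ENSMUSG00000036264), a follistatin-like gene, had a log2 change of -3.22 (SE 0.40) on 268, 40, 8 and 1 UMIs in WT replicates 1 and 2 and CKO replicates 1 and 2, and Adamts16, a secreted metalloprotease, of -2.33 (SE 0.37). Oat again had the smallest p (2.33), with 104% free RNA. Biliary secreted ligands (adjusted p = 0.636), YAP targets (0.706), TGF-beta response genes (0.735) and NRF2 targets (0.215) did not pass, though Hmox1, which degrades heme, did over the last list alone (0.016, log2 change 2.05, but 2.07 and -3.24 within the replicate numbers). edgeR called 0 of 10476 genes, with 547 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0827, and DESeq2 called 0. The edgeR count was 136 without CKO replicate 2, 6 without CKO replicate 1, 8 without WT replicate 1 and 7 without WT replicate 2.

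In hepatocyte-like nuclei pericentral and lipid genes were among the groups called with the preset correlation only. The nuclei of each library fell mostly into a cluster of their own, which held 1629 of 1745 in WT replicate 1, 925 of 1077 in WT replicate 2, 918 of 930 in CKO replicate 1 and 1498 of 1616 in CKO replicate 2, so libraries differ in more than these genes. The CKO libraries also differed from each other in sex-biased hepatocyte genes. Of 7 measured male-biased genes, 5 lay below both WT libraries in CKO replicate 1, while 7 lay above in CKO replicate 2. Of 4 measured female-biased genes, 4 lay above both WT libraries in CKO replicate 1 and 1 in CKO replicate 2. Pericentral genes rose as a group in CKO libraries (11 of 13 measured members positive, median log2 change 0.91, 0.79 and 1.01 within the replicate numbers, camera adjusted p = 3.04e-17, 0.603 with an estimated correlation), and 7 of them passed when adjusted over the list alone. Oat, ornithine aminotransferase among them, went from 12.1 ± 0.835 to 42.7 ± 17.5 CPM (log2 change 1.82, SE 0.36; SD, n = 2 each). Lipogenesis genes also rose as a group (10 of 10 positive, median 0.97, 0.96 and 1.10 within the replicate numbers, adjusted p = 3.04e-17, 0.603 with an estimated correlation). Scd1, the main hepatic fatty acid desaturase, went from 496 ± 166 to 1963 ± 589 CPM (1.98, SE 0.42) and Me1, malic enzyme, from 178 ± 36.2 to 436 ± 131 CPM (1.29, SE 0.33; SD, n = 2 each). None of the lipogenesis genes passed over the list alone (smallest 0.056). Fatty acid oxidation genes were higher as a group (11 of 12 positive, median 0.36, adjusted p = 1.04e-05, 0.603 with an estimated correlation), with Cyp4a10, a fatty acid hydroxylase, at 3.14 (SE 0.41) passing over the list alone (0.0109). Within the first replicates the median of this list was 0.01, and with free RNA subtracted the call ended (adjusted p = 0.0721). The pericentral and lipogenesis calls stayed past the threshold with each library left out in turn and with free RNA subtracted (adjusted p = 7.42e-11 and 1.89e-12), and their members had a median of 25.6% and 20.5% of counts from free RNA, with Oat at 84.7% and Scd1 at 89.8%.

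Other hepatocyte groups depended on single libraries or did not pass. NRF2 targets, the antioxidant response genes, were lower as a group (9 of 12 negative, median -0.50, adjusted p = 0.00038, 0.677 with an estimated correlation). Their median was 0.21 within the first and -1.78 within the second replicates, and without CKO replicate 2 the call ended and the direction turned (0.285). Slc7a11, the cystine transporter, had the smallest p of that list (log2 change -2.81, SE 0.76). Periportal genes (adjusted p = 0.0849), bile acid synthesis and transport (0.11), heme synthesis and breakdown (0.209), YAP targets (0.0641), cell cycle genes (0.16) and acute phase genes (0.976) did not pass. Single genes with the smallest p were Cyp4a10, Mbl2 (1.26, SE 0.18), a secreted lectin, Pdgfrl (-2.19, SE 0.32), Mthfd1l (-1.39, SE 0.20), Ppargc1a (-1.20, SE 0.20), a coactivator of gluconeogenic and mitochondrial genes, and Pigr (1.10, SE 0.21). edgeR called 0 of 13377 genes, with 212 at an unadjusted p under 0.05, and DESeq2 called 2. Without CKO replicate 1 the edgeR count was 282 and without CKO replicate 2 it was 15.

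**Figure D3:**
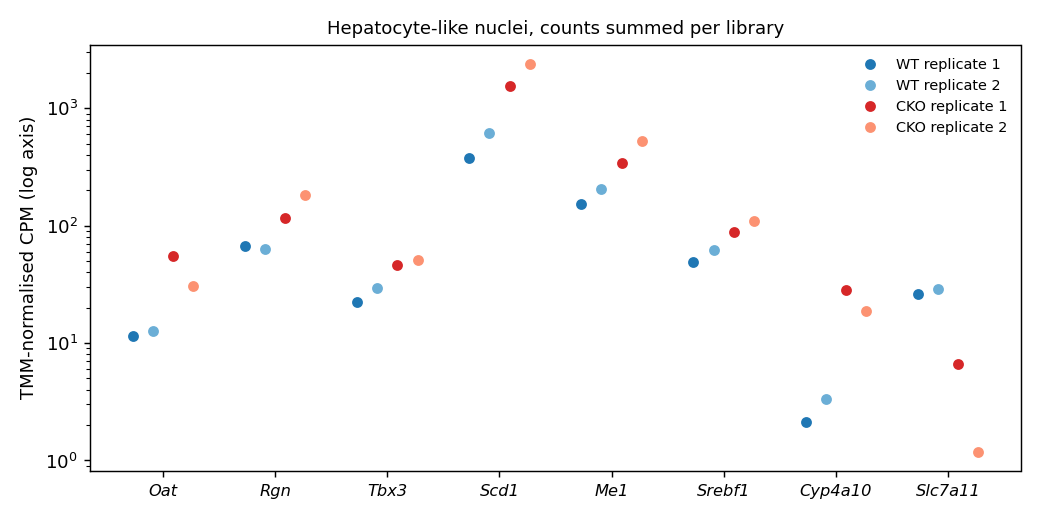
TMM-normalised CPM (log axis) of 8 genes in hepatocyte-like nuclei, with 1 point per library, chosen after their values were seen to show the pericentral, lipogenesis, fatty acid oxidation and NRF2 lists. Scd1 averages 496 CPM in WT and 1963 CPM in CKO libraries, and Slc7a11 27.6 and 3.91 CPM. Estimated free RNA accounted for 89.8% of the Scd1 and 84.7% of the Oat counts, so these points are not mainly RNA of the nuclei.

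Macrophage-like nuclei were compared to see how the inflammatory cells of the injured liver differed. MHC class II genes, which present antigen, were lower as a group in CKO libraries (7 of 7 measured members negative, median log2 change -0.95, -1.14 and -0.48 within the replicate numbers, camera adjusted p = 0.000162, 0.603 with an estimated correlation). H2-Aa (ENSMUSG00000036594) went from 43.8 ± 10.9 to 22.5 ± 1.70 CPM (-0.98, SE 0.30) and Ciita, the regulator of the class, from 79.7 ± 40.0 to 37.3 ± 7.58 CPM (-1.08, SE 0.36; SD, n = 2 each). With free RNA subtracted the list was still called (median -0.90, adjusted p = 0.0281), and the 748 macrophage genes with under 20% free RNA had a median of -0.30. Without WT replicate 1 the call ended (0.507). Kupffer cell identity genes did not pass as a group (adjusted p = 0.118), while 2 of 10 passed when adjusted over the list alone. These were Cd5l, a secreted scavenger protein (log2 change 0.93, SE 0.22, from 214 ± 21.3 to 407 ± 1.18 CPM), and Marco, a scavenger receptor (2.06, SE 0.49), which stood at 2.58 within the first but 0.18 within the second replicates. Ms4a7 (ENSMUSG00000024672), a gene of monocyte-derived macrophages, had a log2 change of -1.95 (SE 0.25), from 106 ± 6.98 to 27.6 ± 1.08 CPM, with an adjusted p of 0.167 over all genes. Oat had the same adjusted p (log2 change 2.21), with 98.1% of its counts from free RNA. The libraries also differed in the clusters that make up this class. The cluster led by Myo5a, Ms4a7 and Ciita held 1053 of 2720 nuclei in WT replicate 1, 203 of 415 in WT replicate 2, 66 of 2227 in CKO replicate 1 and 37 of 171 in CKO replicate 2, and a cluster led by Meg3 and Gpnmb held 2129 nuclei of CKO replicate 1. With values centred per library, which also removes differences between libraries, a cluster led by Gpnmb, St18 and Myo5a held 1224, 232, 1075 and 41 nuclei and the other macrophage cluster 1484, 189, 1148 and 132, in the same order. CKO replicate 1 then had a mix like that of WT libraries. Whether the lower MHC class II and Ms4a7 values reflect the mix of macrophages or a change within cells therefore depends on the clustering and stays open. Cell cycle genes were higher as a group (13 of 18 positive, median 0.59, adjusted p = 0.0108, 0.711 with an estimated correlation), with a median of 73.6% free RNA, and the call ended without WT replicate 1 (0.411, direction turned) or CKO replicate 1 (0.76). Scar- and lipid-associated (adjusted p = 0.298), monocyte (0.706) and interferon response genes (0.0641) did not pass. edgeR called 0 of 12215 genes, with 639 at an unadjusted p under 0.05, and DESeq2 called 2. The edgeR count was 48 without CKO replicate 1, 278 without CKO replicate 2 and 18 without WT replicate 2.

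Estimated free RNA made up, on average, a larger part of the counts in CKO than in WT libraries. Its share of UMIs was 72.0% and 75.5% in WT and 81.0% and 84.5% in CKO endothelial-like nuclei, 67.4% and 74.3% against 76.6% and 79.4% in macrophage-like, 56.6% and 62.5% against 67.1% and 72.8% in mesenchymal-like, 52.3% and 58.7% against 58.6% and 66.0% in cholangiocyte-like, and 28.5% and 33.6% against 32.2% and 39.1% in hepatocyte-like nuclei. In the last 2 classes CKO replicate 1 lies below WT replicate 2. Secreted hepatocyte transcripts were higher as a group in all 5 classes (median log2 change 0.51 to 0.66, adjusted p from 4.64e-06 to 6.08e-05, 0.603 to 0.614 with an estimated correlation). Those calls ended in each class without CKO replicate 2 (0.316 to 0.999) or WT replicate 1 (0.0638 to 0.216). Mitochondrial transcripts were higher in all 5 classes (13 of 13 positive, median 1.29 to 1.54, adjusted p from 1.12e-10 to 1.04e-05, 0.603 to 0.643 with an estimated correlation), and CKO replicate 1 decided them (0.44 to 0.698 without it). Its median barcode held 4.55% mitochondrial UMIs, against 1.58%, 0.438% and 0.616% in WT replicates 1 and 2 and CKO replicate 2. Free RNA accounted for a median of 80.5%, 34.9% and 90.7% of the counts of hypoxia response genes in endothelial-like, hepatocyte-like and macrophage-like nuclei. These genes were higher in endothelial-like (median 0.67, adjusted p = 0.015), hepatocyte-like (0.32, 0.0196) and macrophage-like nuclei (0.51, 0.00595), each 0.603 with an estimated correlation. Without CKO replicate 1 the adjusted p was 0.22, 0.382 and 0.401 in that order, and without WT replicate 1 it was 0.0784, 0.224 and 0.185. The endothelial call also ended without WT replicate 2 (0.0528) and the hepatocyte call without CKO replicate 2 (0.17). Immediate early and heat shock genes passed in no class.

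**Figure D4:**
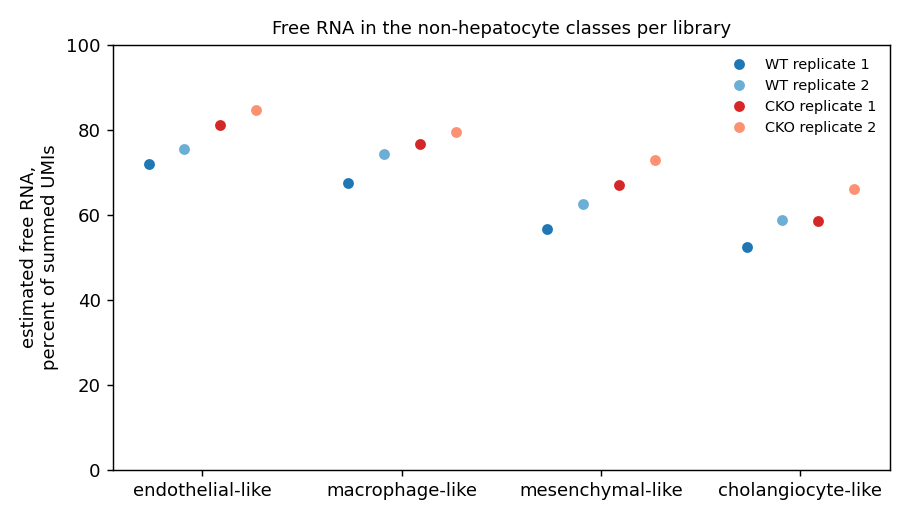
Estimated free RNA in percent of the UMIs summed over each class other than hepatocyte-like, with 1 point per library. The endothelial-like values are 72.0% and 75.5% in WT and 81.0% and 84.5% in CKO libraries.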

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

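All tests in this part were chosen after the results were seen, as were their limits and the sets of lists they use.

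In the classes other than hepatocyte-like, hepatocyte genes had higher and most called lists of the classes' own genes lower values in CKO libraries. For the 83 measured genes of the planned hepatocyte lists that do not scale the estimate (median log2 change 0.34 over these 4 classes), free RNA accounted for a median of 98.9% of the counts. Their median log2 change beyond that of free RNA was -0.030 (SD 0.36 over 308 values, with genes repeated over the classes). These genes thus kept to the proportions found in unnamed barcodes. The estimate takes the secreted hepatocyte transcripts of a class as wholly free RNA, so hepatocyte RNA of any source in the same proportions counts as free. The values therefore do not decide between free RNA and expression within the nuclei themselves. Dilution by a larger share of free RNA could account for the sinusoidal, angiogenic and angiocrine lists. Their 38 members, with genes shared between lists counted again, had a median log2 change 0.10 above that of other endothelial genes with under 20% free RNA (SD 0.34). With free RNA subtracted the list medians were -0.13, -0.05 and -0.03. The 20% level can favour genes higher in WT libraries, so the comparison with other genes leans toward dilution. Dilution alone is argued against for MHC class II genes, which lay at -0.654 from the other genes (SD 0.27) and had -0.90 after against -0.95 before subtraction. That SD is over 7 genes that vary together (estimated correlation 0.872) and does not measure the spread between libraries. Dilution is therefore not excluded for them, since their call also ended without WT replicate 1. It stays open, with lower expression or fewer such nuclei, for the large vessel (-0.249, SD 0.57), fibrillar collagen (-0.068, SD 0.42) and biliary lists (-0.022, SD 0.40), still called with free RNA genes left out (adjusted p = 0.0136, 0.0153 and 0.0402), for the contractile list (-0.015, SD 0.49; median -0.28 after subtraction) and for cell cycle genes of cholangiocyte-like nuclei (-0.256, SD 0.55), still called after subtraction (median -0.65, adjusted p = 0.00296) although all 14 genes together had 5 UMIs in CKO replicate 2.

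The vessel-type endothelial sub-cluster led by Col8a1 was less frequent in CKO livers. Counting error is argued against by the larger of the 2 binomial probabilities at the lower WT share (0.000808). The choice of sub-clusters stays open, since the cluster of all barcodes holding most of these nuclei had a lower share of endothelial-like nuclei in both CKO libraries in 4 of 5 clusterings: 6.34% and 3.11% in WT against 0.358% and 0% in CKO libraries at resolution 1, 10.7% and 13.8% against 4.41% and 2.04% at resolution 2, 10.2% and 5.98% against 5.9% and 0% with at least 1000 genes, and 9.42% and 11.5% against 5.43% and 1.54% without doublet removal, while with values centred per library no such cluster separated. With free RNA subtracted, the summed level of the 50 leading genes changed by -1.265 on the log2 scale (-0.88 and -1.85 within the replicate numbers), against -0.61 (-0.56 and -0.66) for the share of UMIs that is not free RNA. That margin cannot tell dilution by free RNA from fewer such cells.

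CKO replicate 1 differed from the other libraries in sex-biased hepatocyte genes, although all mice are labelled male. All 4 measured female-biased genes lay above both WT libraries there, and 5 of 7 male-biased genes lay below, Mup20 at 401 CPM against 4584 and 5041. A female mouse is argued against by the Y-linked gene Uty, at 208.9 CPM in its hepatocyte-like nuclei against 147 to 249 CPM in the other libraries. The genotype alone is argued against because only 1 of the 9 genes beyond both WT libraries, Cux2, lay on the same side in CKO replicate 2, where 7 of 7 male-biased genes lay above. No other biological explanation was tested.

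The added sequence Neo-PIGCN21AN, which no comparison used, averaged 2.13 CPM in CKO libraries (2.63 and 1.63) against 0.789 and 0.0719 CPM in WT libraries, on 100, 20, 36 and 1 UMIs in that order.

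The median log2 change of cell cycle genes from WT lay above 0 in macrophage-like nuclei (0.41 and 0.06) and below 0 in cholangiocyte-like nuclei (-0.23 and -3.84) of CKO replicates 1 and 2. The averages differ by 2.26, a difference that was not tested. Most of it comes from the value of -3.84, which rests on 5 UMIs, and in CKO replicate 1 alone the difference was 0.63. Within the second replicates the macrophage-like median was -0.28, and free RNA accounted for a median of 73.6% of these counts.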

How the results depend on the processing

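Of the counts, shares and list totals, 195 values stayed the same under an alternative and 35 moved. A share that turned in sign without passing counts as the same. The hepatocyte-like log2 change of 0.38 among all kept barcodes, for example, was -0.008 with the replicate block. Of the lists by class, 666 kept their side of the threshold, 35 came to pass, 114 ceased to pass and 9 reversed, with the main or the alternative value past it. A change of direction between values that do not pass is counted among the 666. Of the named genes and subtypes, 402 stayed, 102 came to pass and 9 ceased to pass. edgeR called 0 genes in every class, and the number called under alternatives was as follows. In endothelial-like nuclei it was 1 with DESeq2, 50 with no count filter and 0 to 184 with a library left out. In mesenchymal-like nuclei it was 1 with DESeq2, 42 with at least 1000 genes per nucleus, 4 with free RNA genes left out, 84 with no count filter and 11 to 330 with a library left out. In cholangiocyte-like nuclei it was 3 with at least 1000 genes, 3 with free RNA genes left out, 68 with no count filter and 6 to 136 with a library left out. In hepatocyte-like nuclei it was 2 with DESeq2 and 0 to 282 with a library left out. In macrophage-like nuclei it was 2 with DESeq2, 139 with at least 1000 genes, 1 with free RNA genes left out, 80 with no count filter and 0 to 278 with a library left out. Where a library is left out, the remaining one of its group is assumed to vary like the other group. With the replicate number as a replicate block the count was 21 in endothelial-like, 8 in macrophage-like and 0 in other nuclei, and 29 lists were called. Under this block the endothelial sub-clusters led by Csmd1 and by Slc45a4 had an adjusted p of 0.0771 and 0.131 (0.0112 and 0.0168 without it), and that led by Col8a1 one of 0.0179. Deviations of libraries with the same replicate number correlated at 0.086 to 0.297. The number of lists called, 27 of 68, was 0 with an estimated correlation, 0 with fry, 9 of 56 tested with free RNA subtracted (chosen after seeing the data), 5 of 24 tested with free RNA genes left out and 18 to 31 with a library left out. Of the 27, 8 of the 26 still tested kept their call with free RNA subtracted, 4 of 9 with free RNA genes left out, 27 under the replicate block and 13 to 24 with a library left out. Lists that reversed, with adjusted p, were mitochondrial transcripts in cholangiocyte-like nuclei with free RNA subtracted (0.691) and hepatocyte secreted genes in macrophage-like nuclei with free RNA subtracted (0.107). Without CKO replicate 2, hepatocyte secreted genes reversed in cholangiocyte-like (0.629), hepatocyte-like (0.316) and macrophage-like nuclei (0.999), as did NRF2 targets (0.285) and cell cycle genes (0.00012) in hepatocyte-like nuclei. Acute phase genes in hepatocyte-like nuclei reversed without WT replicate 2 (0.00431), and cell cycle genes in macrophage-like nuclei without WT replicate 1 (0.411). With a library left out these lists ranged, in adjusted p, from 1.2e-27 to 0.629, 2.39e-11 to 0.316 and 6.27e-18 to 0.999 for the secreted genes in the same order, from 7.23e-15 to 0.285 for NRF2 targets, from 2.39e-11 to 0.743 for hepatocyte cell cycle, from 0.000243 to 0.316 for acute phase and from 0.000524 to 0.76 for macrophage cell cycle genes. The cause was not tested. The limits of 300 genes and 1000 UMIs removed no barcode and so test nothing, although their values are counted above among those that stayed. Cholangiocyte-like nuclei of CKO replicate 2 (95085 UMIs) limit depth most.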

Other observations

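Sub-clusters of mesenchymal-like nuclei differed in frequency between the genotypes in tests chosen after the data were seen. A sub-cluster led by Lsamp, Rbfox1 and Colec10 made up 25.6% ± 5.99 in WT and 7.02% ± 1.98 in CKO livers (SD, n = 2 each), a log2 change of -1.79 (SE 0.38, edgeR adjusted p = 0.0255). It had 5 of 6 stellate markers raised over the other sub-clusters. A sub-cluster led by Ptprt, Tafa1 and Neto1 made up 17.1% ± 0.918 and 33.3% ± 2.61 (0.97, SE 0.29, adjusted p = 0.0445), and one led by Csmd3, Ebf1 and C7 made up 5.17% ± 0.975 and 2.11% ± 0.189 (-1.37, SE 0.43, 0.0445). In the same comparison the Ptprt sub-cluster had 1 of 6 stellate markers raised. The Csmd3 sub-cluster had 0 of 6, with 3 of 8 portal fibroblast markers raised. A sub-cluster led by Sult1e1, Sgk2 and Adamts4 made up 11.9% ± 0.72 and 32.2% ± 6.97 (1.41, SE 0.33, 0.0255). Sult1e1 also led a cluster of unnamed barcodes that resemble free RNA, and the sub-cluster had the hepatocyte gene Cyp2b9 among its leading genes and 0 of 6 stellate markers raised over the other sub-clusters. The free RNA share of the class was 56.6% and 62.5% in WT and 67.1% and 72.8% in CKO libraries, and this sub-cluster was not separated from such RNA. The Lsamp and Sult1e1 calls ended without WT replicate 1 (adjusted p = 0.246 for both), WT replicate 2 (0.0895 and 0.131) or CKO replicate 2 (0.0651 and 0.0977), and the Ptprt call ended with any library left out (0.114 to 0.29), as did the Csmd3 call (0.126 to 0.375).

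The vessel-type endothelial sub-cluster led by Slc45a4, Vegfc and Mecom made up 10.6% ± 1.12 in WT and 15.9% ± 2.32 in CKO livers (SD, n = 2 each; log2 change 0.61, SE 0.19, edgeR adjusted p = 0.0168). The call ended without WT replicate 1 (0.0687), CKO replicate 1 (0.642) or CKO replicate 2 (0.0953).

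EYFP, an added reporter sequence, had 265, 8, 20 and 39 UMIs, and eGFPcre 54, 0, 5 and 4 UMIs, in WT replicates 1 and 2 and CKO replicates 1 and 2. In WT replicate 1, EYFP was found in 2.82% of cholangiocyte-like (95% Clopper-Pearson interval 2.03 to 3.81%) and 1.29% of unnamed barcodes (1.01 to 1.63%), with median depths of 2912 and 1948 UMIs. The labels do not describe these sequences.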
